A study of Mus musculus with 20 samples.

How the data were processed

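Gene expression of single cells was measured in 20 libraries, 1 for each of 4 prostate lobes of 5 mice aged 6 months, 3 of C57BL/6J and 2 of FVB/NJ. Per the submitters' processing notes, the authors aligned reads to mm10 and counted them with Cell Ranger 2.2.0, and the deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and barcode. Those values were used as raw counts. The deposited matrices hold 27998 genes and 28401 barcodes. Strain, lobe and replicate number come from the sample labels. Within a strain the lobes of a mouse share a replicate number, so lobes were paired by design, while strains were not. Residual profiles of libraries with the same number correlated with a median r of 0.0517 (30 pairs, -0.0380 to 0.202), and those with different numbers with -0.0370 (48 pairs). Residuals were taken from means of 2 or 3 mice, which makes the 2 kinds of pairs balance each other. The second value is therefore no separate evidence, the pairs are not independent, and the pairing rests on the labels.

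Barcodes with at least 500 detected genes and at most 20% mitochondrial UMIs were kept (20 and 98 barcodes failed), and 226 doublets called by scrublet within libraries (0.799%) were removed, which left 28064 cells. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen with the library as batch key, and cells were grouped with 40 principal components, 15 neighbours and Leiden clustering at resolution 1 with seed 1 and no integration (scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Python 3.11.15). Each of 28 clusters took the class whose fixed markers had the highest mean z (log2 CPM standardised over clusters). At least 3 markers of that class had to be detected in at least 10% of cells, each with a z of at least 0.5. The 10 leading genes of a cluster (present in at least 20% of cells, pseudocount 5 CPM) were checked for markers of other classes. Cluster 13, with pericyte markers but smooth muscle genes leading, and cluster 21, with neuronal genes, stayed unnamed; the neuronal list was written after the clusters were seen. Names end in "-like" because they rest on expression alone, and the groups of cells compared were formed from the same data.

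Raw counts were summed per library and class, with at least 20 cells per sum. Lobe contrasts, each lobe minus the mean of the other 3, used edgeR 4.0.16 (R 4.3.3) with TMM normalization, filterByExpr and quasi-likelihood tests on the means of 8 groups of strain and lobe. Strain contrasts within lobes and the 3 interaction terms used the same fit. The luminal strain difference over lobes used limma 3.58.1 (trend, robust) on the mean over lobes of each mouse's log2 CPM with a prior count of 2, and the basal, fibroblast and myeloid strain differences used edgeR on sums per mouse. Proximal and secretory luminal-like cells were compared in edgeR with the mouse as a term and without the markers of both classes. The fits of lobe contrasts, of strain contrasts within lobes and of the interaction held no mouse term and treated the libraries of a mouse as independent. The mouse as a block was an alternative for the lobe contrasts and the interaction. In the other fits the mouse is the replicate or a term. Fibroblast-like sums reached 20 cells only in the anterior (5 mice) and dorsal lobe (4 mice), so those lobes alone were compared. Adjusted p are Benjamini-Hochberg values with a threshold of 0.05. A fitted log2 change averages logs over lobes and so differs from a ratio of mean CPM; a ratio alone is given where a fitted group held no UMI, which leaves no standard error, or where the lower group held 3 UMIs or fewer. Where a group held no UMI a floor of 3 counts over the group gives a lower bound, and with 1 to 3 UMIs a pooled ratio is given with its 95% counting interval. This interval covers the counting of UMIs alone and not the variation between mice. Shares of classes were tested by exact permutation, over 1024 choices of a lobe per mouse or over 10 splits of the mice.

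Comparisons, cell type markers, gene lists and the rule for named genes were fixed before the data were examined. The list of neuronal genes, 3 tests of explanations, the search for T-cell and plasma-cell RNA and the added alternatives were chosen after. Mitochondrial, Rpl, Rps and Gm-numbered genes were not named. The rule names the 6 largest rises per lobe in luminal-like cells (CPM of at least 50, at least 2-fold, in each mouse), 5 per lobe in basal-like and fibroblast-like cells leaving out genes at least 5 times as high in secretory luminal-like cells, 10 strain genes each way in luminal-like cells (CPM of at least 20, no overlap between strains) and 5 each way in other classes, 8 each way for proximal cells, the 3 lowest interaction p, and 2 to 4 members per list. The 16 lists cover secreted proteins, androgen response, endoplasmic reticulum and secretory stress, polyamines, zinc and metallothioneins, oxidative phosphorylation, glutathione and detoxification, interferon response, antigen presentation, complement and chemokines, WNT, BMP and FGF signals, matrix, position and lineage factors, immediate-early and heat-shock genes, seminal vesicle, and blood. They were tested with camera at a preset correlation of 0.01 and with an estimated one. Genes whose last 400 transcript bases share at least 50% of 31-base words with another gene are called uncertain. Coordinates are from GENCODE mouse release 21 on mm10. Alternatives, whose effects the closing section gives, were DESeq2 1.42.0 size factors and tests (a likelihood ratio test for the interaction), no count filter or a filter of 10 counts in 5 libraries or 3 mice, each mouse left out, the mouse as a block, lobes combined the other way, other cell filters (at most 10% mitochondrial UMIs, at least 300 or 1000 genes, doublets kept), resolutions 0.5 and 2, at least 50 cells per sum, classes thinned to equal totals, genes abundant in luminal-like cells left out, and other denominators of shares.

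In simulated data 200 genes were changed 2-fold or 4-fold, and the percents recovered are given in that order. They were 91% and 100% for the luminal anterior contrast and 92% and 99% for the basal anterior contrast. Other lobe contrasts of these classes were not simulated. Luminal strain fits gave 34% and 95% within the anterior lobe, 93% and 100% over lobes, and 10% and 86% for the interaction. Fibroblast lobes gave 44% and 87%. Basal, fibroblast and myeloid strain differences gave 29% and 89%, 21% and 87%, and 28% and 84%, and proximal cells 47.5% and 88%. Libraries were drawn independently with the same dispersion for each gene and no mouse effect. Only well-counted genes were changed, so real rates can be lower. Small strain differences in single lobes and in rare classes are therefore under-called.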

Results

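Droplet-based single-cell RNA sequencing was applied to the anterior, dorsal, lateral and ventral lobes of the prostate of 5 mice aged 6 months, 3 of strain C57BL/6J and 2 of strain FVB/NJ. The lobes are separate glands that empty into the urethra, and each was made into its own library. This gave 20 libraries with 1 mouse per strain and replicate number. The deposited matrices held 28401 barcodes, 837 to 2149 per library, with 5078616 to 30185082 unique molecular identifiers (UMIs) per library. After filtering, 28064 cells remained, 822 to 2147 per library, with a median of 3913 to 17815.5 UMIs and 1427 to 2682.5 genes per cell. The design addresses which cell classes and genes differ between lobes, which differ between strains, and whether lobe differences depend on the strain. Nnt, which carries a known deletion in C57BL/6J, was lower in C57BL/6J than in FVB/NJ libraries of each lobe, summed over the kept cells of a library, with 1.95 ± 0.590 against 4.55 ± 1.15 CPM (UMI counts scaled by library size; mean ± SD, n = 3 and 2 mice) in the anterior lobe. The libraries read the 3-prime end of transcripts, so this compares levels and is no proof of a label. Glo1 reached 43.6 ± 1.06 and 42.3 ± 2.27 CPM in the same libraries.

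Most cells were epithelial. Clusters with the fixed markers of secretory luminal cells, the columnar cells that make prostatic fluid, held 19008 cells (67.7%) and basal-like clusters 5430 (19.3%). Clusters with markers of proximal luminal cells such as Krt4 and Psca held 1434 (5.11%). Fibroblast-like cells numbered 1220 (4.35%), endothelial-like 268, myeloid-like 265, smooth muscle-like 245 and ionocyte-like, with the proton pump genes Atp6v1g3 and Atp6v0d2 and the factor Foxi1, 76. The anterior lobe was rich in fibroblast-like cells, 13.1% ± 7.39 of a library against 1.29% in the mean of the other lobes (n = 5 mice, higher in 5 of 5). The ventral lobe was poor in basal-like cells, 5.66% ± 2.46 against 23.3% (lower in 5 of 5). Proximal luminal-like cells made up 13.7% ± 12.03 of ventral libraries against 1.30% elsewhere, higher in 5 of 5 mice. Myeloid-like cells made up 1.83% ± 0.865 of anterior libraries against 0.670%, also in 5 of 5. Smooth muscle-like cells made up 2.58% ± 2.47 of lateral libraries against 0.392%, higher in 4 of 5 mice. These 5 differences passed a 2-sided exact permutation test over the arrangements of lobes within mice. Benjamini-Hochberg adjusted p in this exact permutation test was 0.0313 for the fibroblast, proximal, myeloid and smooth muscle classes and 0.0375 for the basal class, among 32 comparisons of class and lobe. Within epithelial cells the ventral basal difference was -20.8 percentage points and did not pass (adjusted p = 0.0563 in the exact permutation test). The myeloid difference turned to -14.3 percentage points when shares were taken among non-epithelial cells, where the anterior fibroblasts enter the denominator. Ventral secretory luminal-like shares (79.1% ± 13.8 against 65.6%) and anterior ones (54.6% ± 11.1 against 73.7%) did not pass, with adjusted p of 0.279 and 0.0885 in the same exact permutation test. Dissociation and droplet capture can set each of these shares.

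In the mean over lobes, FVB/NJ libraries held fewer secretory luminal-like cells and more basal-like, smooth muscle-like and ionocyte-like cells. Averaged over the 4 lobes of each mouse, the secretory luminal-like share was 56.5% ± 1.90 in FVB/NJ (n = 2) and 77.2% ± 3.45 in C57BL/6J (n = 3). The basal-like share was 26.8% ± 0.0710 and 13.7% ± 1.74, the smooth muscle-like share 1.92% ± 0.133 and 0.283% ± 0.197, in the same order, and the ionocyte-like share 0.607% ± 0.0739 and 0.0270% ± 0.0256. The anterior lobe went the other way for 2 of them, with 57.6% secretory luminal-like cells in FVB/NJ and 52.7% in C57BL/6J, and 25.3% and 28.4% basal-like cells. Mouse means of the strains did not overlap for these 4 classes. The exact permutation p was 0.1 for each, the smallest that 10 splits of 3 and 2 mice allow, so p under 0.05 cannot be reached. Proximal luminal-like shares were 7.81% ± 0.392 in FVB/NJ and 2.12% ± 2.06 in C57BL/6J (exact permutation p = 0.2). Fibroblast-like shares were 3.85% ± 0.878 and 4.51% ± 3.54 (p = 1 in the same exact test). In the ventral lobe the proximal share was 25.2% ± 2.39 in FVB/NJ and 6.06% ± 8.20 in C57BL/6J, where 207 of 233 such cells came from mouse 2. Clusters were formed without integration, so several classes were held by other clusters in each strain. Basal-like cells of C57BL/6J lay mostly in cluster 0 and those of FVB/NJ in clusters 12 and 22. Ventral proximal luminal-like cells of FVB/NJ lay in cluster 27 (90.9%). Those of C57BL/6J lay mostly in cluster 4, which is a trait of 1 library, since 183 of its 190 cells come from mouse 2.

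**Figure D1:**
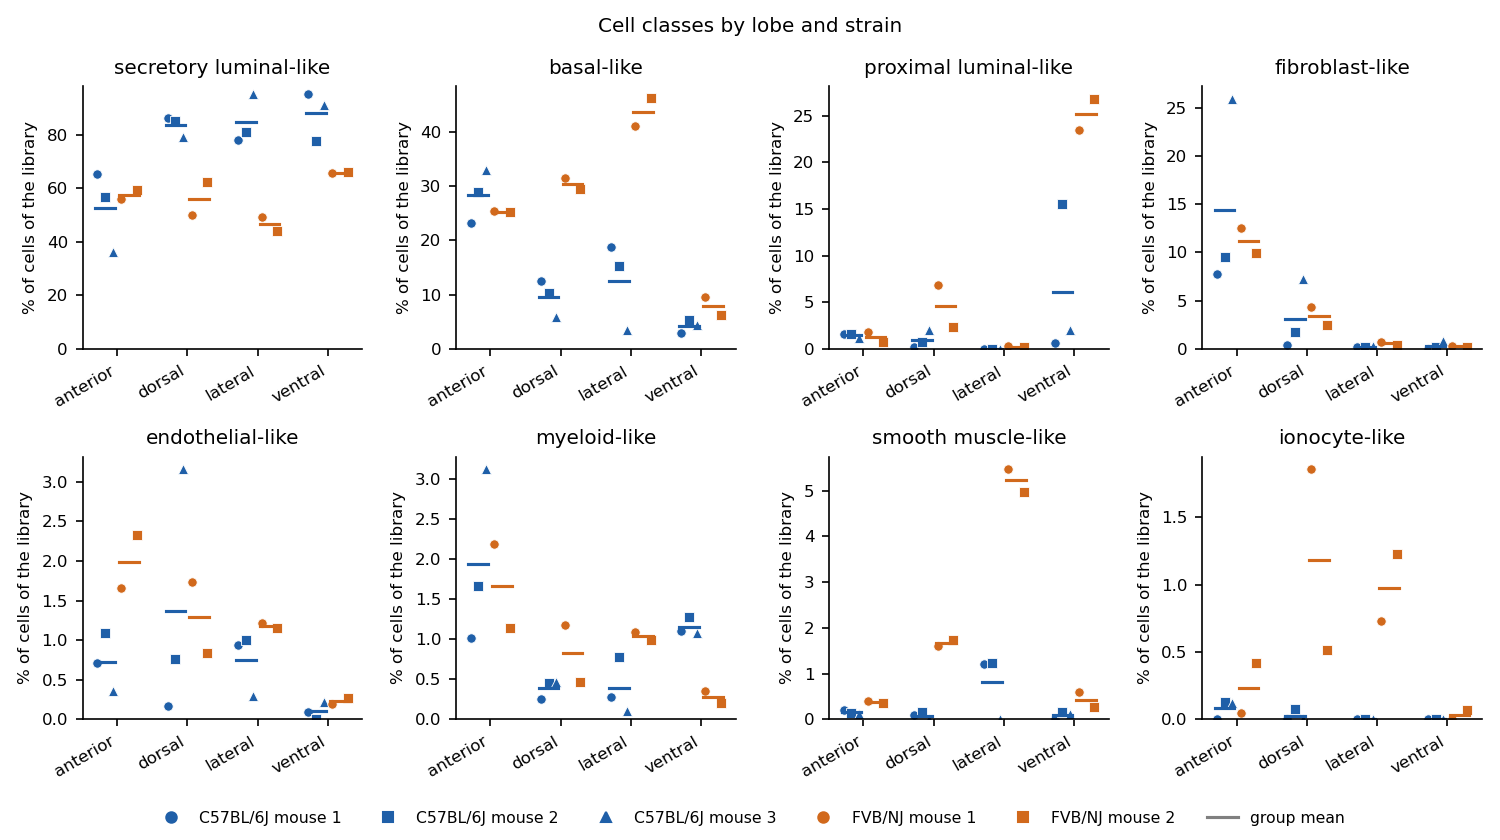
Share of each of 8 cell classes in percent of the cells of a library (vertical axis) by lobe (horizontal axis), 1 point per library, with blue for C57BL/6J, orange for FVB/NJ, marker shape for the mouse and a bar for the mean of a strain in a lobe. Anterior fibroblast-like shares averaged 13.1%, ventral basal-like shares 5.66%, and FVB/NJ ventral proximal luminal-like shares 25.2%.

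Secretory luminal-like cells differed between lobes in a large part of the transcriptome. Of 12435 genes tested with edgeR's quasi-likelihood test on counts summed per library, 6899 differed in the anterior lobe from the mean of the other 3 lobes (3541 higher, 3358 lower). The counts were 6524 in the dorsal (3448 higher, 3076 lower), 6384 in the lateral (3456 higher, 2928 lower) and 9372 in the ventral lobe (4836 higher, 4536 lower). At a change of at least 2-fold the counts were 2028, 1433, 1596 and 3787. Leaving out FVB/NJ mouse 2 lowered the dorsal count to 4059. In FVB/NJ dorsal libraries 29.7% and 17.5% of these cells lay in cluster 15, which FVB/NJ lateral cells lead. Without cells in clusters led by another lobe, the dorsal count was 7221. In each group another cluster held most luminal-like cells. These were for C57BL/6J clusters 3, 6, 19 and 24 and for FVB/NJ clusters 16, 20, 15 and 26 in the anterior, dorsal, lateral and ventral lobes.

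Anterior luminal-like cells expressed Ren1, which encodes renin, the protease that cleaves angiotensinogen (chromosome 1, 133350510 to 133360325), at 3194 ± 2843 CPM against 0.198 ± 0.158 CPM in the mean of the other lobes (n = 5 mice), a 16113-fold ratio. Its level was 4832 to 5751 CPM in the 3 C57BL/6J anterior libraries and 126 and 75.0 CPM in the FVB/NJ ones. The other genes named by the fixed rule were 9530003J23Rik (816 ± 110 CPM, 180-fold), C1s2 (ENSMUSG00000079343; 315 ± 94.7 CPM, 29.3-fold) and C1rb (817 ± 141 CPM, 7.87-fold), relatives of the complement proteases C1s and C1r. They also included Glb1l3, a beta-galactosidase relative (351 ± 61.6 CPM, 9.42-fold), and 9530053A07Rik (log2 change 8.84 ± 0.21 SE, edgeR adjusted p = 7.04e-17), which at 35297 CPM was also high in the dorsal lobe. C1rb at 311 CPM and Glb1l3 at 111 CPM were also expressed there, so their ratios to the mean of the other lobes overstate the difference from the dorsal lobe. C1rb shares 68.9% of its transcript end with C1ra, so its level is uncertain. Of 18 measured glutathione and detoxification genes, 13 fell and 3 rose (14 and 3 adjusted over the list alone). Among them were the plasma glutathione peroxidase Gpx3 (-5.63 ± 0.46, log2 ± SE), the retinaldehyde dehydrogenase Aldh1a1 (-4.18 ± 0.26) and the carbonyl reductase Cbr2 (-3.54 ± 0.21). The camera set test with its preset correlation gave adjusted p = 0.000944 for this list and 0.203 with an estimated correlation. Endoplasmic reticulum and secretory stress genes rose for 14 of 20 members with 0 falling (15 and 1 adjusted over the list alone). The chaperones Hyou1 (1.12 ± 0.11) and Pdia4 (1.08 ± 0.10) led them, with camera adjusted p = 0.0335 and 0.923 with an estimated correlation. Most genes of this list fell in the ventral lobe, which enters this contrast. Of 19 interferon-response genes 12 fell and 0 rose (11 and 0 without the ventral library of C57BL/6J mouse 2, which was rich in these transcripts), including the antiviral Oas1a (-3.42 ± 1.02) and Ifit1 (-2.68 ± 0.67; camera adjusted p = 0.133). Among 16 antigen presentation genes 4 rose, the class II genes H2-Aa (2.62 ± 0.48), Cd74 (2.55 ± 0.39), H2-Ab1 (2.24 ± 0.41) and H2-Eb1 (2.17 ± 0.52), and 9 fell. These 4 are also myeloid markers, and H2-Eb1 stood at 1.07 CPM in luminal-like and 4289 CPM in myeloid-like cells. Myeloid-like cells were a larger share of anterior libraries, so RNA of those cells is not excluded as the source of the rise.

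Dorsal luminal-like cells were marked by Tgm4, the prostate transglutaminase that cross-links seminal proteins into the copulatory plug (chromosome 9, 123034726 to 123067561), at 16727 ± 2759 CPM (8.11 ± 0.18, edgeR adjusted p = 4.5e-17). This level was close to the 14621 CPM of the anterior lobe and far above the 50.3 to 99.5 CPM of C57BL/6J lateral libraries. The cornified-envelope gene Sprr2f reached 234 ± 151 CPM (45.3-fold over the mean of the other lobes), and the NOD-like receptor gene Nlrp10 69.1 ± 20.8 CPM (20.6-fold). Tcaf3, of the TRP channel-associated factors, reached 76.8 ± 27.6 CPM (10.9-fold). A630095E13Rik reached 4749 ± 3564 CPM (9.05 ± 0.18, 55.6-fold in mean CPM), which is uncertain because 69.6% of its transcript end is shared with Gm49367. Of 12 zinc and metallothionein genes 7 rose and 1 fell (7 and 2 adjusted over the list alone). They include the zinc importers Slc39a8 (2.73 ± 0.14) and Slc39a4 (1.66 ± 0.17) and the exporter Slc30a2 (1.46 ± 0.21; camera adjusted p = 0.0359, and 0.25 with an estimated correlation). Of 17 oxidative phosphorylation genes 13 fell and 1 rose by small amounts, such as Uqcrc2 (-0.42 ± 0.08; camera adjusted p = 0.0395, 0.98 with an estimated correlation). Of 12 polyamine genes 4 rose, led by the antizyme inhibitor Azin1 (1.28 ± 0.09), and 4 fell, 1 of which passed with the mouse as a block.

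Lateral luminal-like cells expressed Msmb, which encodes beta-microseminoprotein, a major prostatic secretory protein (chromosome 14, 32142023 to 32158370), at 13709 ± 3316 CPM against 1111 ± 722 CPM in the mean of the other lobes (4.73 ± 0.54, edgeR adjusted p = 6.26e-07). The salivary gene Smgc (chromosome 15, 91838265 to 91861438) reached 62.8 ± 29.1 CPM (21.4-fold) and the beta-defensin Defb10 84.2 ± 29.1 CPM (16.8-fold). The calmodulin-binding Pcp4 reached 510.3 ± 120 CPM (log2 4.31 ± 0.38 SE, 6.76-fold in mean CPM, with 182 CPM in the dorsal lobe). The claudin Cldn10 reached 115 ± 57.3 CPM (log2 4.27 ± 0.20, 2.53-fold in mean CPM, with 123.5 CPM in the ventral lobe). Endoplasmic reticulum and secretory stress genes rose for 14 of 20 members with 0 falling (16 adjusted over the list alone). Among them were Hsp90b1 (1.004 ± 0.111), Dnajb11 (0.95 ± 0.08) and Manf (0.94 ± 0.11), with camera adjusted p = 0.000616 and 0.944 with an estimated correlation. The fall of most genes of this list in the ventral lobe enters this contrast too. Of 20 genes of the androgen response list 10 rose and 5 fell. Homer2 (2.21 ± 0.11) and Steap4 (2.204 ± 0.395) rose and the protease Tmprss2 fell (-2.197 ± 0.074; camera adjusted p = 0.697). Of 9 measured WNT, BMP and FGF signal genes 5 rose and 1 fell, led by Wnt4 (3.33 ± 0.23) and Wnt5a (2.02 ± 0.31; camera adjusted p = 0.13). The heat-shock genes Hspa1b (-3.04 ± 0.44) and Hspa1a (-2.83 ± 0.41), which handling can raise, were among 6 of 16 immediate-early and heat-shock genes that fell, while 4 rose.

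Ventral luminal-like cells were dominated by a few secretory transcripts. Spink1, a Kazal-type trypsin inhibitor of seminal fluid (chromosome 18, 43728082 to 43737557), took 241860 ± 66162 CPM against 179 ± 222 CPM (14.47 ± 0.60, edgeR adjusted p = 8.31e-14). Sbp, which encodes spermine-binding protein (chromosome 17, 23941672 to 23945607), took 193189 ± 35278 CPM against 26.0 ± 28.4 CPM (14.86 ± 0.42, edgeR adjusted p = 2.66e-16). Its neighbour Sbpl (12.92 ± 0.23) lay at 236, 220 and 336 CPM in the C57BL/6J ventral libraries and at 88623 and 111811 CPM in the FVB/NJ ones. The secretoglobin gene Scgb2b27 averaged 346 ± 223 CPM and had no UMI in the other lobes, at least 18153-fold higher against a floor of 3 counts over those libraries. Its relative Scgb2b7 was 42005-fold higher in pooled counts (95% counting interval 14373 to 203689, 3 UMIs in the other lobes), with 119 to 3447 CPM in C57BL/6J and 4.52 and 18.4 CPM in FVB/NJ. The interval leaves out this spread between mice. The protease inhibitor gene Spink5 was 762-fold higher (1313 ± 793 CPM). Interferon-response genes rose for 17 of 19 members with 0 falling, led by Ifit1 (4.16 ± 0.37), Oas1a (4.11 ± 0.41) and Rtp4 (3.37 ± 0.40; camera adjusted p = 0.096). In C57BL/6J mouse 2 these transcripts took 770 CPM of ventral secretory luminal-like cells, against 315 and 175 CPM in mice 1 and 3. Without that library 13 of 19 rose and 0 fell, with Ifit1 at 3.86 ± 0.35 and Oas1a at 3.81 ± 0.40. Of 16 immediate-early and heat-shock genes 11 rose, led by Egr1 (2.65 ± 0.23), Ier2 (2.30 ± 0.17) and Btg2 (2.28 ± 0.11; camera adjusted p = 0.0179, 0.671 with an estimated correlation). Secretory stress genes fell for 17 of 20 members, with Hyou1 (-1.87 ± 0.13), Trib3 (-1.85 ± 0.15) and Pdia4 (-1.85 ± 0.12; camera adjusted p = 0.00111, 0.671 with an estimated correlation). Oxidative phosphorylation genes rose for 10 of 17 members and fell for 3. Glutathione and detoxification genes rose for 11 of 18, led by Cbr2 (6.95 ± 0.14). Of 12 zinc genes 7 fell, led by Mt3 (-7.24 ± 0.56) and Slc30a2 (-6.12 ± 0.32). Among 16 measured position and lineage factors, Hoxa13 (3.04 ± 0.26) and Hoxb13 (2.46 ± 0.10), homeobox genes of the posterior body, rose and Gata2 fell (-4.63 ± 0.24). Gata2 rose in the anterior (1.77 ± 0.16) and dorsal lobes (2.39 ± 0.15), and Hoxd13 rose in the anterior lobe (1.47 ± 0.32).

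Other lists moved in both directions between lobes. Of the 20 genes of the secretory protein list, 19 passed in the anterior lobe (7 higher, 12 lower), 13 in the dorsal (7 and 6), 13 in the lateral (5 and 8) and 16 in the ventral lobe (9 and 7). In the anterior lobe the median of this list was -1.91 while camera ranked it upward (adjusted p = 0.369). In the dorsal and lateral lobes camera gave adjusted p = 0.00314 and 0.0453 (0.25 and 0.944 with an estimated correlation). Complement and chemokine genes included the neutrophil chemoattractants Cxcl2 (4.07 ± 0.22) and Cxcl1 (2.96 ± 0.25), higher in the ventral lobe, and C1ra, higher in the anterior lobe (4.57 ± 0.23). In that lobe 4 of 13 members rose and 4 fell. Of 7 measured matrix genes 2 rose and 2 fell in the ventral lobe, among them Col6a3 (4.09 ± 0.32). Of the seminal vesicle list 1 of 8 members was measured, Pate4, and it was higher in the anterior lobe (log2 median of the list 6.24). Of 5 blood genes Alas2 fell in the anterior lobe (-0.78 ± 0.20), and in the lateral lobe 4 rose once the mouse was a block against 0 without it. No camera call between lobes in luminal-like cells held with an estimated correlation.

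**Figure D2:**
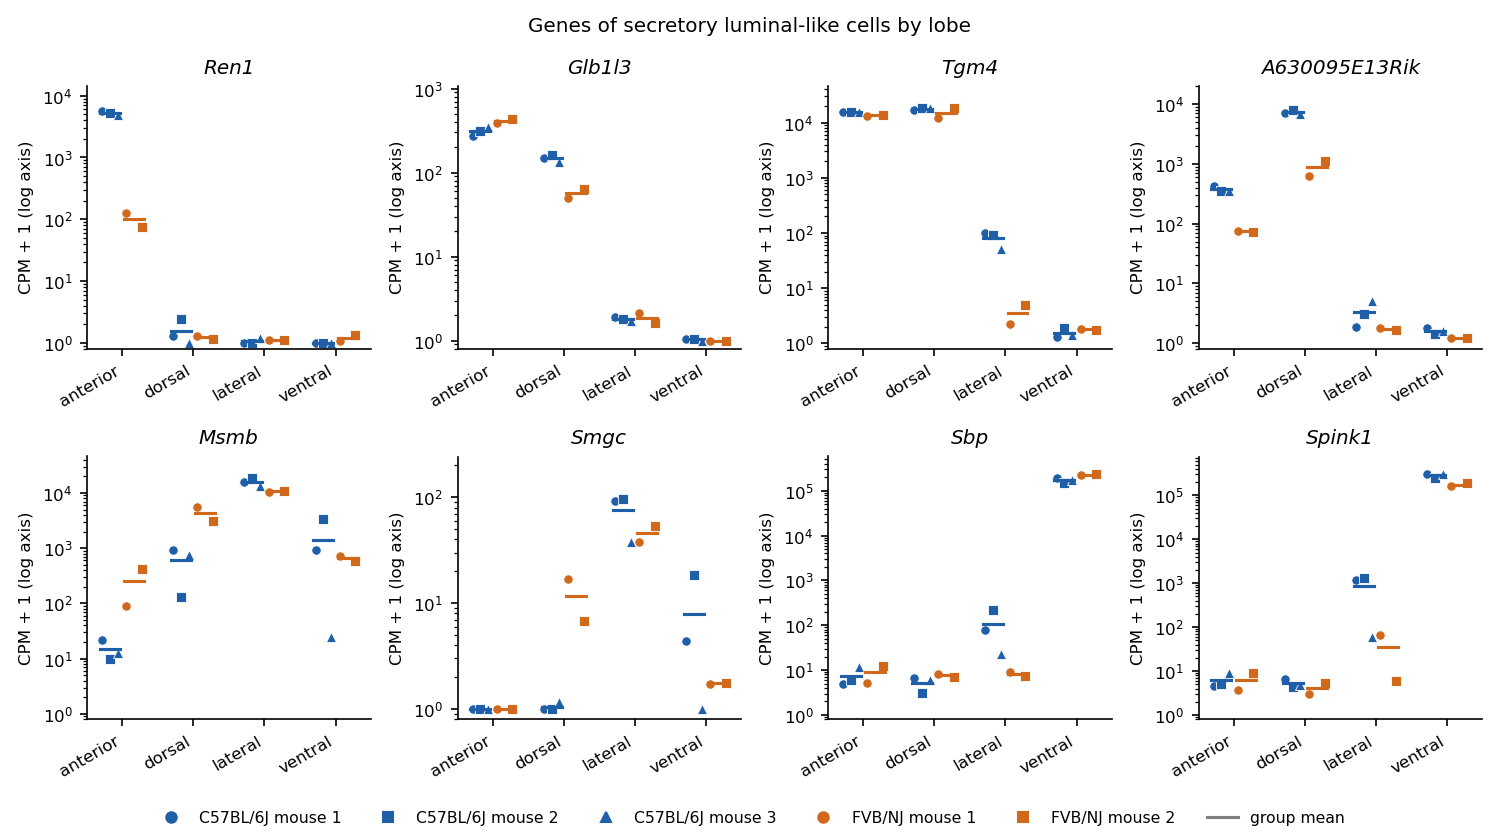
Expression of 8 genes in secretory luminal-like cells in CPM plus 1 (vertical axis, log scale) by lobe (horizontal axis), 1 point per library, with blue for C57BL/6J, orange for FVB/NJ, marker shape for the mouse and a bar for the mean of a strain in a lobe. Ren1 lay between 4832 and 5751 CPM in C57BL/6J anterior libraries and at 126 and 75.0 CPM in FVB/NJ ones, and Sbp averaged 193189 CPM in the ventral lobe.

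Between strains, luminal-like cells differed most in genes that were close to absent in 1 strain. Averaged over the 4 lobes of each mouse, the phosphodiesterase gene Gdpd3 (chromosome 7, 126766334 to 126775649) stood at 137 ± 6.85 CPM in FVB/NJ (n = 2) and 0.255 ± 0.0736 CPM in C57BL/6J (n = 3; log2 8.41 ± 0.18 SE, limma adjusted p = 2.82e-09). The lectin intelectin, Itln1 (chromosome 1, 171518122 to 171535294), stood at 848 ± 154 against 1.16 ± 0.421 CPM (8.002 ± 0.142). The complement inhibitor Cd59a stood at 214 ± 1.41 against 0.582 ± 0.185 CPM (7.81 ± 0.29) and the microsomal glutathione transferase Mgst1 at 195 ± 12.6 against 4.51 ± 0.877 CPM (4.77 ± 0.17). The antimicrobial ribonuclease Ang4 (5.61 ± 0.27), Sbpl (5.02 ± 0.16), Ccdc80 (3.98 ± 0.23), BC023719 (6.56 ± 0.17) and Eif3j2 (4.01 ± 0.09) were also higher in FVB/NJ. So was Hist1h2al (5.34 ± 0.19), which is uncertain because of near-identical histone genes. BC023719 is annotated as an antisense transcript, and whether strand was used in counting is not given in the sources used here. In C57BL/6J, Ms4a5 (chromosome 19, 11273238 to 11283873) reached 523 ± 131 CPM against 1 UMI in the FVB/NJ cells, a pooled ratio of 46504 (95% counting interval 8346 to 1.84e+06). The protease inhibitor Wfdc3 stood at 2136 ± 337 CPM in C57BL/6J and 35.7 ± 33.4 CPM in FVB/NJ (-4.93 ± 0.56, limma adjusted p = 0.00785), and its call was lost without the ventral library of C57BL/6J mouse 2 (-4.37, adjusted p = 0.0976). The kinase gene Camk2b stood at 26.1 ± 3.28 and 0.311 ± 0.0719 CPM (-5.59 ± 0.15) and the class I gene H2-Q10 at 121 ± 44.3 and 0.613 ± 0.0552 CPM (-3.01 ± 0.18). Lamtor3 (-3.20 ± 0.09), the snoRNA host gene Snhg12 (-2.95 ± 0.08), Btg3 (-2.90 ± 0.11), the zinc-alpha-2-glycoprotein gene Azgp1 (-2.64 ± 0.08) and Eif3j1 (-2.46 ± 0.07), an initiation factor subunit, were lower in FVB/NJ. So was Rnaset2b (-5.95 ± 0.10), uncertain because 51.4% of its transcript end is shared with other genes (48.5% with Rnaset2a). Eif3j1 and Eif3j2 changed in opposite directions, while their summed level was 0.873 times as high in FVB/NJ as in C57BL/6J. A shift of reads between these 2 genes is therefore not excluded, although their transcript ends shared 0% by the measure used here.

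Over lobes, 3970 of 12435 genes differed between strains by limma (2190 higher in FVB/NJ, 1780 lower), 953 of them at least 2-fold. Values of the 3 and 2 mice did not overlap for 7312 genes (58.8%), where chance gives 20% (2 of 10 splits). Of the secretory stress list 13 of 20 genes fell in FVB/NJ and 0 rose (15 adjusted over the list alone). Examples are Dnajc3 (-0.85 ± 0.09) and Hyou1 (-0.71 ± 0.09), with camera adjusted p = 0.000256 and 0.889 with an estimated correlation. Antigen presentation genes rose for 8 of 16 members and fell for 1, led by the class I gene H2-Q7 (2.55 ± 0.25) and by the class II gene H2-Ab1 (1.67 ± 0.46). H2-Eb1 fell (-1.76 ± 0.39; camera adjusted p = 0.00976 for the list, 0.889 with an estimated correlation). H2-Eb1 is a myeloid marker at 1.07 CPM in luminal-like cells and fell in FVB/NJ myeloid-like cells too (-4.48 ± 0.23), so RNA of those cells is not excluded. Of 7 matrix genes 5 rose, among them Col6a3 (1.40 ± 0.34) and Sparc (1.38 ± 0.20; camera adjusted p = 0.0122, 0.889 with an estimated correlation). Within single lobes edgeR called 2022, 2617, 3885 and 2201 genes between strains in the anterior, dorsal, lateral and ventral lobes. Without FVB/NJ mouse 1 the count over lobes was 1711 and the counts by lobe 826, 1122, 1823 and 910. Without FVB/NJ mouse 2 they were 2108 over lobes and 968, 1480, 2124 and 838 by lobe. Without C57BL/6J mouse 2 the anterior count was 1342.

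The strain difference itself depended on the lobe for 2337 of 12435 genes (edgeR quasi-likelihood test of 3 interaction terms), for 2816 with the mouse as a block, and for 240 of 6204 when the cell classes of a library were thinned to equal totals. The lowest p belonged to Ablim1, which encodes an actin-binding LIM protein (chromosome 19, 57032733 to 57314919; F = 209, adjusted p = 1.26e-10). FVB/NJ exceeded C57BL/6J in the dorsal lobe, 30.9 ± 1.28 against 10.9 ± 0.421 CPM (1.47 ± 0.15). It was below C57BL/6J in the lateral, 2.05 ± 0.0199 against 10.7 ± 2.45 CPM (-2.36 ± 0.21), and ventral lobe, 0.429 ± 0.0572 against 12.6 ± 2.12 CPM (-4.72 ± 0.23). Adi1, an enzyme of the methionine salvage pathway (F = 99.8, adjusted p = 5.14e-08), was higher in FVB/NJ in the anterior (1.001 ± 0.155) and dorsal lobes (1.31 ± 0.16). It was lower in the lateral (-0.49 ± 0.15) and ventral lobe, in the latter 20.2 ± 1.69 against 78.6 ± 4.70 CPM (-1.84 ± 0.14). Vnn1, which encodes the pantetheine hydrolase vanin 1 (F = 93.4, adjusted p = 6.17e-08), was higher in FVB/NJ in the anterior lobe, 41.0 ± 4.04 against 0.0264 ± 0.0458 CPM, and in the dorsal lobe, 37.4 ± 7.68 against 0.330 ± 0.0371 CPM. In the lateral lobe its levels were 0.450 ± 0.0114 and 0.477 ± 0.339 CPM. Leaving out C57BL/6J mouse 2, FVB/NJ mouse 1 or FVB/NJ mouse 2 lowered the count of interaction genes to 1416, 453 or 636.

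**Figure D3:**
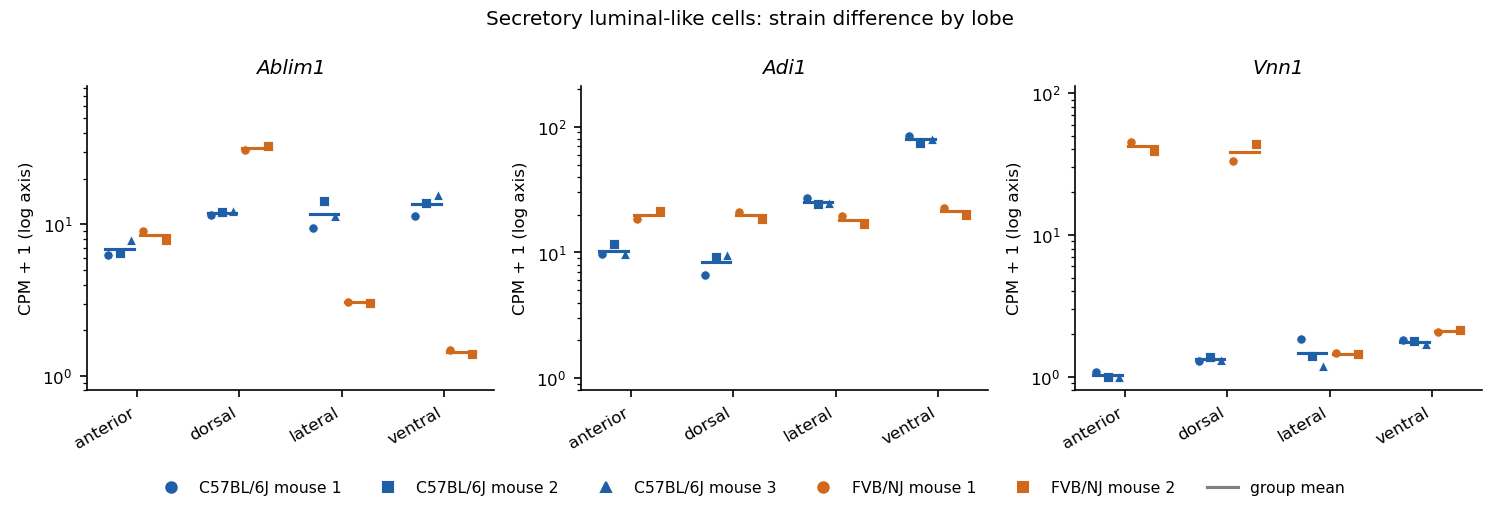
Expression of Ablim1, Adi1 and Vnn1 in secretory luminal-like cells in CPM plus 1 (vertical axis, log scale) by lobe (horizontal axis), 1 point per library, with blue for C57BL/6J, orange for FVB/NJ, marker shape for the mouse and a bar for the mean of a strain in a lobe. Ventral Ablim1 averaged 0.429 CPM in FVB/NJ and 12.6 CPM in C57BL/6J, while dorsal Ablim1 averaged 30.9 and 10.9 CPM.

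Basal-like cells carried their own lobe differences. In the anterior lobe, Ivl, which encodes the cornified-envelope protein involucrin, rose (2.82 ± 0.31, 76.6 ± 33.01 against 14.96 ± 8.496 CPM, n = 5 mice). So did the chemokine scavenger receptor Ackr3 (2.41 ± 0.13, 231 ± 52.2 against 44.3 ± 12.9 CPM, edgeR adjusted p = 9.14e-16), the aquaglyceroporin Aqp3 (1.99 ± 0.14), the methyltransferase Inmt (1.95 ± 0.15) and the carboxypeptidase Scpep1 (1.92 ± 0.26). In the dorsal lobe Cyp2f2 (1.83 ± 0.20), Lhfp (1.76 ± 0.18), the growth-factor binding Igfbp5 (1.74 ± 0.18, 172 ± 24.5 against 49.99 ± 25.7 CPM), and the keratins Krt75 (1.63 ± 0.21) and Krt19 (1.40 ± 0.15) rose. Krt19 and Cyp2f2 are also among the proximal luminal markers, and Krt19 had 2.66 times the basal level in secretory luminal-like cells. The lateral lobe had 4 genes past the rule, Psca (3.30-fold in mean CPM, adjusted p = 0.00114), the glutathione peroxidase Gpx2 (1.17 ± 0.20), Cpeb2 (1.15 ± 0.12) and the alcohol dehydrogenase Adh1 (1.09 ± 0.15). The call of Psca was lost with the DESeq2 test (adjusted p = 0.0880) and without C57BL/6J mouse 2 (0.0526 in the edgeR test). Psca stood at 863 CPM in proximal luminal-like cells and 30.4 CPM in basal-like cells. In the ventral lobe smooth muscle actin Acta2 (3.23 ± 0.21, 133 ± 47.9 against 18.5 ± 3.79 CPM), Medag (2.08 ± 0.24), the chemokine Cxcl14 (1.85 ± 0.17), the potassium channel Kcnn4 (1.71 ± 0.15) and the matrix protein Smoc2 (1.71 ± 0.16) rose. Acta2, Cxcl14 and Smoc2 stood at 10428, 957 and 773 CPM in smooth muscle-like cells. Those cells made up 0.223% of ventral and 2.58% of lateral libraries, so their share did not follow the ventral rise.

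Of 7514 genes tested in basal-like cells, edgeR called 1963 in the anterior (1129 higher), 639 in the dorsal (416 higher), 496 in the lateral (219 higher) and 330 in the ventral lobe (168 higher). Immediate-early and heat-shock genes rose in the anterior lobe for 9 of 16 members with 0 falling, led by Egr1 (1.49 ± 0.10) and Fos (0.74 ± 0.11; camera adjusted p = 3.66e-06, 0.0684 with an estimated correlation). They fell in the lateral lobe for 8 of 16 with 0 rising, such as Fosb (-0.82 ± 0.13) and Nr4a1 (-0.81 ± 0.11; camera adjusted p = 4.86e-15, 0.0103 with an estimated correlation). Position and lineage factors rose in the anterior lobe for 7 of 14 members, with Gata2 (1.55 ± 0.30), Hoxd13 (1.15 ± 0.11) and Hoxd11 (1.11 ± 0.17; camera adjusted p = 0.00151, 0.0239 with an estimated correlation). Secretory protein transcripts rose for 7 of 16 members in the ventral lobe, Sbp by 10.83 ± 0.18 and Spink1 by 10.14 ± 0.17 (camera adjusted p = 4.55e-33, 1.28e-05 with an estimated correlation), the genes that dominated luminal-like cells of that lobe. In the dorsal lobe the median of the same list was -0.20 while camera ranked it upward (adjusted p = 1.56e-11, 8.38e-05 with an estimated correlation). The complement and chemokine list fell in the lateral lobe for 3 of 6 members, with Cxcl14 at -1.67 ± 0.18 (camera adjusted p = 0.000549, 0.0335 with an estimated correlation). In the anterior lobe 3 of 6 matrix genes fell, led by Fbln2 (-2.56 ± 0.43; camera adjusted p = 0.00303, 0.0239 with an estimated correlation). The counts changed with the mice included. Without C57BL/6J mouse 1, C57BL/6J mouse 2, FVB/NJ mouse 1 or FVB/NJ mouse 2 they were 267, 251, 187 or 220 in the dorsal, 320, 285, 289 or 186 in the lateral and 197, 175, 165 or 134 in the ventral lobe. The anterior count was 1242 or 995 without either FVB/NJ mouse.

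Fibroblast-like cells of the anterior lobe expressed Wnt2, a secreted signal (chromosome 6, 17988940 to 18030585), at 137 ± 10.5 CPM (n = 5) against 3.26 ± 3.78 CPM in the dorsal lobe (n = 4). The pooled ratio was 33.5 with a 95% counting interval of 11.4 to 163 on 3 dorsal UMIs. The transcription factor Hand2 (pooled ratio 41.4, 7.34 to 1644 on 1 UMI), Tmem108 (55.1, 9.79 to 2183 on 1 UMI), Pmaip1, a pro-apoptotic BH3-only gene (124 ± 55.8 CPM, 21.9-fold), and Kctd1 (80.1 ± 26.7 CPM, 13.1-fold) were also higher in the anterior lobe. Dorsal fibroblast-like cells had more of the growth-factor protease Pappa2 (6.38 ± 0.61, 107 ± 64.7 against 1.18 ± 1.87 CPM). They had more of the matrix genes Cilp (47.6-fold) and Lum, which encodes lumican (chromosome 10, 97565128 to 97572703; 4.58 ± 0.34, 350.5 ± 189.9 against 12.9 ± 8.09 CPM). The same held for the estrogen sulfotransferase Sult1e1 (5.05 ± 0.47, edgeR adjusted p = 1.06e-06) and the homeobox gene Mkx (4.82 ± 0.48). Of 21 matrix genes 6 were lower and 2 higher in the anterior lobe (9 and 2 adjusted over the list alone). Among the lower were Lum, Tnc (-3.77 ± 0.59), Col6a3 (-3.03 ± 0.27) and Fbln1 (-2.87 ± 0.21), with camera adjusted p = 1.66e-07 and 0.363 with an estimated correlation. Of 15 WNT, BMP and FGF signal genes 5 were higher and 3 lower. Bmp7 (3.44 ± 0.57) and the WNT antagonist Sfrp2 (2.68 ± 0.39) were higher and Sfrp1 was lower (-2.13 ± 0.34; camera adjusted p = 0.228). The complement gene C3 (-1.68 ± 0.47) and the chemokine Cxcl12 (-1.66 ± 0.32) were among 4 of 12 complement and chemokine genes that were lower (camera adjusted p = 0.0245, 0.491 with an estimated correlation). Secretory transcripts of luminal cells moved with the lobe here too, with 5 of 9 lower in the anterior lobe, led by Msmb (-3.77 ± 0.92).

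In total 580 of 6050 genes differed between anterior and dorsal fibroblast-like cells (254 higher and 326 lower in the anterior lobe). Anterior cells lay mostly in cluster 7 (94.0% in C57BL/6J) and dorsal cells in cluster 10 (73.8% in C57BL/6J, 53.3% in FVB/NJ), which Lum, Sult1e1 and Fbln1 lead. Lateral and ventral libraries held too few of these cells to test. Without FVB/NJ mouse 1 the call of Cilp was lost (adjusted p = 0.268 in the edgeR test). Leaving out C57BL/6J mouse 3 or FVB/NJ mouse 1 lowered the count to 320 or 196.

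**Figure D4:**
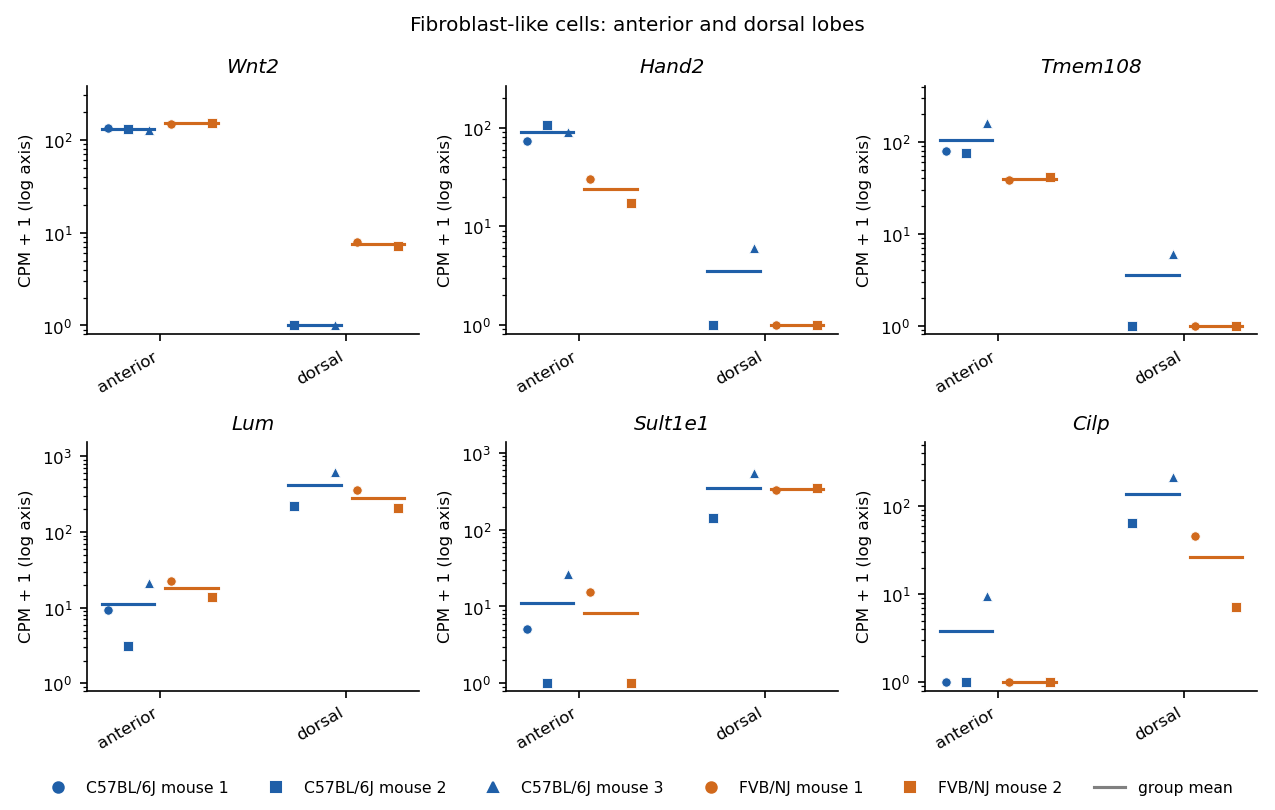
Expression of 6 genes in fibroblast-like cells in CPM plus 1 (vertical axis, log scale) in the anterior and dorsal lobes (horizontal axis), 1 point per library with at least 20 such cells, with blue for C57BL/6J, orange for FVB/NJ, marker shape for the mouse and a bar for the mean of a strain in a lobe. Wnt2 averaged 137 CPM in the anterior and 3.26 CPM in the dorsal lobe, and Lum 12.9 and 350.5 CPM.

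The strains also differed in the other cell classes. Sums per mouse mix lobes unequally, with 55.8% anterior cells among C57BL/6J and 28.5% among FVB/NJ basal-like cells (1184 of 2120 and 944 of 3310). Lobe differences therefore enter the basal counts, while the basal genes named here passed with lobes averaged too. Myeloid-like sums were unequal as well, with 27.9% ventral cells in C57BL/6J (39 of 140) and 8% in FVB/NJ (10 of 125). Lobes could not be averaged for that class, so lobe differences are not excluded from its strain genes and lists. In basal-like cells summed over lobes, Padi3, a peptidylarginine deiminase of keratinising epithelia, was higher in FVB/NJ (6.81 ± 0.25, 99.7 ± 0.375 against 0.917 ± 0.561 CPM, n = 2 and 3 mice, edgeR adjusted p = 8.32e-11). So were the class I gene H2-Q7 (6.04 ± 0.29), 1600014C10Rik (5.82 ± 0.25), Gdpd3 (pooled ratio 201, 95% counting interval 35.9 to 7965 on 1 UMI) and BC023719 (at least 111-fold against a floor of 3 counts over C57BL/6J). Scpep1 (chromosome 11, 88924020 to 88955465) was lower, 10.8 ± 1.70 against 576 ± 65.4 CPM (-5.80 ± 0.16). Also lower were the chromatin protein gene Hmga1 (-4.73 ± 0.27), Snhg12 (-4.23 ± 0.15), the cytidine deaminase Apobec3 (-3.93 ± 0.20) and the uncertain Rnaset2b (-5.28 ± 0.24). In fibroblast-like cells Gdpd3 was at least 337-fold higher in FVB/NJ, 502 ± 42.5 CPM against 0. Eif3j2 (3.54 ± 0.24), Cd59a (3.71 ± 0.36), Psmc3ip (pooled ratio 22.1, 5.78 to 187 on 2 UMIs) and BC023719 (pooled ratio 119, 40.3 to 578 on 3 UMIs) were higher too. Hmga1 (-4.56 ± 0.50), AA467197 (pooled ratio 27.7, 7.30 to 235 on 2 UMIs) and Rnaset2b (pooled ratio 66.9, 18.1 to 559 on 2 UMIs) were lower in FVB/NJ. The plasma-cell marker Jchain (1074 ± 1072 CPM in C57BL/6J) and the myeloid marker H2-Eb1 (34.8 ± 32.2 CPM) passed as lower too but are not read as fibroblast differences. Jchain gave 823, 324, 179 and 438 UMIs in C57BL/6J libraries with 153, 2, 3 and 2 of these cells and 0 in the anterior libraries with 148 and 216. Its call was lost without FVB/NJ mouse 1, where the log2 change was still large (-12.6). H2-Eb1 stood at 4289 CPM in myeloid-like and 16.9 CPM in fibroblast-like cells, with a log2 change of -5.81 in the latter. Its call was lost with the DESeq2 test (-6.11), with at most 10% mitochondrial UMIs (-5.79) and without FVB/NJ mouse 1 or 2 (-4.62 or -7.88). With lobes averaged the call was lost too and the change was smaller (-2.70). At resolution 2 a T-cell cluster took 26 of the 1220 fibroblast-like cells. In myeloid-like cells FVB/NJ had more of the chemokine Cxcl13, 324 ± 237 against 1.84 ± 3.19 CPM (edgeR adjusted p = 0.00295). Its pooled ratio was 167, with a 95% counting interval of 29.5 to 6616 on 1 UMI in C57BL/6J. Also higher were the chemokine Cxcl5 (4.95 ± 0.58), Gdpd3 (4.39 ± 0.53), Ifitm1 (3.70 ± 0.64) and Eif3j2 (3.34 ± 0.70). FVB/NJ had less H2-Eb1 (chromosome 17, 34305867 to 34316674, log2 change -4.48 ± 0.23, 345 ± 81.3 against 8410 ± 1319 CPM). It also had less AA467197 (-2.93 ± 0.59), Rnaset2b (-3.08 ± 0.50), lipoprotein lipase Lpl (63.4 ± 36.2 CPM in C57BL/6J, 2 UMIs in FVB/NJ) and Ren1 (-5.19 ± 0.96), which had 4.22 times the myeloid level in secretory luminal-like cells. Without C57BL/6J mouse 1 the calls of Cxcl13, Ifitm1, Eif3j2, Ren1 and Rnaset2b were lost (adjusted p = 0.0545, 0.0846, 0.0874, 0.0678 and 0.0590 in the edgeR test). Their log2 changes there were 9.47, 3.51, 3.78, -4.53 and -3.12, similar to or larger than those with each mouse included. Without C57BL/6J mouse 2 the calls of Ren1 (-5.23) and AA467197 (-2.37) were lost (edgeR adjusted p = 0.0727 and 0.0932). Without FVB/NJ mouse 1 the call of Ifitm1 (3.14) was lost. With doublet calls kept those of Lpl and AA467197 were lost (0.0547 and 0.0640). In fibroblast-like cells Psmc3ip and AA467197 lost their calls without either FVB/NJ mouse and with lobes averaged.

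The counts were 1843 of 9505 genes in basal-like (869 higher in FVB/NJ, 974 lower), 195 of 6803 in fibroblast-like (100 and 95) and 68 of 2547 in myeloid-like cells (37 and 31). Antigen presentation genes rose in FVB/NJ for 5 of 14 members in basal-like cells (camera adjusted p = 5.05e-08, 0.566 with an estimated correlation). They rose for 4 of 16 in myeloid-like cells (camera adjusted p = 0.00161, 0.2 with an estimated correlation). Examples in both classes are H2-Q4 (1.30 ± 0.12 and 1.90 ± 0.20) and H2-K1 (1.21 ± 0.10 and 1.68 ± 0.17), while H2-Eb1 was the 1 member that fell in each. Interferon-response genes fell in FVB/NJ fibroblast-like cells for 5 of 16 members with 0 rising (8 adjusted over the list alone), led by Rsad2 (-2.99 ± 0.59) and Ifit3 (-2.31 ± 0.43; camera adjusted p = 1.03e-06, 0.648 with an estimated correlation). Luminal-like and basal-like cells shared 378 genes higher and 323 lower in FVB/NJ where independent lists would share 157 and 136, while 120 and 57 changed in opposite directions. The classes come from the same mice, so the lists are not independent. In the tests of all 4 classes 24 genes passed in the same direction, among them Gdpd3 and Cap1. Sbpl, Wfdc3, Ren1 and H2-Eb1 passed too. All of these but H2-Eb1 are abundant in secretory luminal-like cells, and H2-Eb1 is in myeloid-like cells, so RNA of those cells is not excluded in the other classes. Rnaset2a, Rnaset2b, Rpl29 and Gm10709 are also among the 24 and are uncertain because of near-identical copies. In each class Eif3j2 was higher and Eif3j1 lower in FVB/NJ, so a shift of reads between them is not excluded there either. Myeloid counts without C57BL/6J mouse 1, 2 or 3 were 20, 27 and 132, and fibroblast counts without FVB/NJ mouse 1 or 2 were 39 and 64. Basal counts without C57BL/6J mouse 1, FVB/NJ mouse 1 or FVB/NJ mouse 2 were 1219, 1104 and 1018. Limma on lobe means gave 428 genes in basal-like and 43 in fibroblast-like cells.

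Proximal luminal-like cells were compared with secretory luminal-like cells of the same mice. They had more of the membrane repair gene Myof (6.04 ± 0.42, 129 ± 132 against 0.999 ± 0.278 CPM, n = 5 mice, edgeR adjusted p = 3.19e-05), the mitochondrial carrier Slc25a48 (5.99 ± 0.44) and the peptidoglycan receptor Pglyrp1 (5.74 ± 0.68). They had more of the scaffold Ahnak (5.15 ± 0.46, 782 ± 344 against 17.7 ± 10.4 CPM), the matricellular Ctgf (5.04 ± 0.49), the keratin Krt6a (4.41 ± 0.39), the integrin subunit Itgb6 (4.36 ± 0.32). The gasdermin Gsdmc2 was higher too (7.49 ± 0.52) but is uncertain because 68.2% of its transcript end is shared with related genes. They had less 9530003J23Rik (-4.58 ± 0.55), the metallothionein Mt3 (-4.24 ± 0.60), Itln1 (-3.61 ± 0.33), Ms4a5 (-3.51 ± 0.82), the defensin Defb1 (-3.02 ± 0.78), Scgb2b27 (-2.77 ± 0.40), Plac8 (-2.76 ± 0.38) and the uncertain A630095E13Rik (-4.17 ± 0.80). Of the proximal cells 77.8% (1116 of 1434) were ventral, while the secretory cells come from each lobe, so genes of a lobe, such as 9530003J23Rik and A630095E13Rik, move with the makeup of lobes. Against secretory cells drawn from the same libraries their changes were -3.36 and -2.80, that of Itln1 was -1.13, and Defb1 did not pass (-1.21, adjusted p = 0.117 in the edgeR test). Mt3, Ms4a5 and Plac8 also shrank (-3.08, -2.69 and -1.83), while Scgb2b27 fell further (-4.45). Among the higher genes, Gsdmc2 (6.01), Pglyrp1 (4.59) and Ahnak (4.495) shrank, and Slc25a48 and Ctgf shrank less. Myof stayed nearly the same, and Krt6a (4.79) and Itgb6 (4.44) were somewhat larger. Ms4a5 lost its call with the DESeq2 test and without C57BL/6J mouse 2, Defb1 without C57BL/6J mouse 2 or 3, and Scgb2b27 with at least 300 genes per cell and at resolution 2. Endoplasmic reticulum and secretory stress genes were lower for 16 of 20 members and higher for 1, among them Creld2 (-1.70 ± 0.47) and Pdia4 (-1.58 ± 0.29; camera adjusted p = 1.75e-05, 0.67 with an estimated correlation). The position factors Hoxd13 (3.39 ± 0.35), Hoxd11 (3.04 ± 0.50) and Klf5 (1.43 ± 0.24) were higher, 4 of 14 in all (camera adjusted p = 0.0534). Of 18 glutathione and detoxification genes 7 were higher, led by Gpx2 (2.79 ± 0.47; camera adjusted p = 0.0429, 0.67 with an estimated correlation). The chemokines Cxcl15 (4.40 ± 0.42) and Cxcl17 (3.83 ± 0.22), the class I gene H2-Q7 (2.05 ± 0.49) and Pmepa1 (3.42 ± 0.43), an androgen response list member, were also higher. Outside the markers of both classes, 2992 of 11781 genes differed (1479 higher, 1513 lower). The classes were formed from expression itself and Myof, Slc25a48, Pglyrp1, Ahnak, Krt6a and Gsdmc2 are leading genes of cluster 8. These differences therefore describe the groups of cells and do not test that the groups exist. Without C57BL/6J mouse 2 or FVB/NJ mouse 1 the count was 1810 or 1735.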

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

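The tests of a response of the whole library, of free RNA of lateral cells and of lateral tissue in the dorsal dissection, and the values without the ventral library rich in interferon genes or without luminal-like cells of another lobe's clusters, were chosen after the results were seen. A difference between groups was tested directly by the interaction of strain and lobe in luminal-like cells: 2337 genes passed, and F was 209 for Ablim1, 99.8 for Adi1 and 93.4 for Vnn1. A signal outside the comparisons was seen in 2 unnamed clusters. Cluster 13 held 100 cells with pericyte genes such as Rgs5 beside the smooth muscle genes Myl9 and Myh11, and cluster 21 held 18 cells with the neuronal genes Npy, Prph, Tubb3 and Stmn2, 15 from C57BL/6J dorsal and 3 from C57BL/6J lateral libraries.

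In proximal luminal-like cells, cluster 4 was rich in interferon-response genes, and 183 of its 190 cells came from the ventral library of C57BL/6J mouse 2. Immune cell RNA or doublets with immune cells are argued against: immune marker transcripts were 1.53 times as high as in the other proximal cells of C57BL/6J ventral libraries (59.1 and 38.6 CPM, against 33780 CPM in myeloid-like cells), under the bound of 2 set beforehand. A response of the whole library is possible, but the test in basal-like cells cannot decide it. Its interferon genes were picked as low in basal-like cells of the other C57BL/6J ventral libraries, which favours a high ratio. Those genes stood at 249 CPM (77 UMIs) in basal-like cells of that library, 2.34 times the mean of the others (66.6 and 146 CPM). Secretory luminal-like cells of that library held 770 CPM of the list against 315 and 175 CPM. What set off such a response in 1 mouse was not tested.

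In FVB/NJ dorsal libraries 240 of 808 and 234 of 1334 secretory luminal-like cells lay in cluster 15 with the lateral cells. Lateral genes were 21.5 and 39.1 times as high (median) as in other luminal-like cells of the same libraries, which restates the grouping. Free RNA of lateral cells adds transcripts and removes none. The 6 named dorsal genes were 0.126 and 0.130 times as high (median) in these cells, which held 19230.5 and 15497 UMIs per cell against 9216 and 7778. Free RNA added to dorsal cells at their usual level would not lower these genes so far. Low dorsal genes also enter the grouping, however, so this is no independent test and free RNA is not excluded. Lateral tissue in the dorsal dissection and dorsal cells of a lateral type in this strain cannot be told apart. Lateral basal-like cells (cluster 22) per such luminal-like cell were 0.246 and 0.769 in dorsal and 0.383 and 0.744 in lateral libraries, a ratio of means of 0.901, which both explanations allow.

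Genes that differ 8-fold or more between strains in luminal-like cells may in part reflect reads shared between near-identical copies: 25% of them (15 of 60) share their transcript end with another gene, against 2.30% of other tested genes (284 of 12352; Fisher exact p = 7.55e-12). For Rnaset2a and Rnaset2b the summed level was 0.895 times as high in FVB/NJ as in C57BL/6J, while Rnaset2b alone was 0.0118 times as high. Sums of other pairs were 0.873 (Eif3j1 and Eif3j2, with 0% shared by this measure), 0.892 (H2-Q10 and H2-K1, where H2-K1 holds most of the sum and the closest copies are other genes), 0.643 (Rpl29 and Gm10709), 1.91 (Sbp and Sbpl) and 289.7 (Cd59a and Cd59b), so shared reads do not account for each of them. Loss of FVB/NJ reads against a C57BL/6J reference is argued against as the whole cause, because 45% of these genes (27 of 60; 95% interval 32.1 to 58.4) were lower in FVB/NJ. Strain differences in expression stay open and were not tested apart from genotype.

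Lobe labels were also permuted within mice. In luminal-like cells 2 of 60 splits, the real one included, gave as many genes as the 6899 of the anterior lobe (highest other 7714). The shares were 1 of 60 for the 6524 of the dorsal (985), 2 of 60 for the 6384 of the lateral (6549) and 1 of 60 for the 9372 of the ventral lobe (4726). Each is under 0.05 without correction for the number of contrasts. Labels of the 4 lobes were permuted together, so other splits mix lobes that differ strongly, and their median count was 0. The shares therefore argue against free exchange of all lobe labels and cannot decide on a single lobe. In basal-like cells 1 of 80 splits did so for the anterior (1963, highest other 238), 1 of 80 for the dorsal (639, 201), 1 of 80 for the lateral (496, 164) and 3 of 80 for the ventral lobe (330, 1325). The split with 1325 genes took the same lobe from 5 of 5 mice, and those with 7714 and 6549 from 4 of 5, so they repeat the structure of the lobes. For fibroblast-like cells (580, highest other 4) and proximal cells (2992, highest other 0) 16 splits are too few for a share under 0.05, and 1 of 16 gave as many genes in each.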

How the results depend on the processing

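The alternatives added after the data were seen were secretory cells from the libraries of the proximal cells, luminal-like cells of another lobe's clusters left out, the interferon cluster of proximal cells left out, the shallowest library (C57BL/6J anterior, mouse 3) left out, the ventral library rich in interferon genes left out, and fibroblast-like cells with T-cell or plasma-cell RNA (29) left out. Of 119 pairs of a named gene and its comparison, 102 stayed past the threshold under each alternative in which the gene was tested. This includes left-out mice, and 0 pairs reversed. The rule for named genes took the largest changes, with the same direction in each mouse or no overlap between strains. Reversals were therefore unlikely from the outset, and the 102 of 119 do not describe unselected genes. Genes named only for the interaction or as list members are not among the pairs. With a mouse left out alone, calls were lost for Cilp (fibroblast lobes), Jchain (fibroblast strain) and Cxcl13, Eif3j2, Ifitm1, Ren1 and Rnaset2b (myeloid strain). Under other alternatives they were lost for Psca (lateral basal), H2-Eb1, Psmc3ip and AA467197 (fibroblast strain), Lpl and AA467197 (myeloid strain), Ms4a5, Scgb2b27 and Defb1 (proximal) and Wfdc3 (luminal strain). Counts of genes stayed within 1.5 times in 225 of 242 other planned comparisons, 45 of 46 added later and 54 of 95 with a mouse left out. The mouse as a block changed no other call than those given. Without a count filter more genes were tested, and the fibroblast strain count was 454 and the myeloid 187. With the DESeq2 test the basal strain count was 1116. With lobes combined the other way the basal and fibroblast strain counts were 428 and 43, and the cause of these changes was not tested. Thinned to equal totals, which leaves fewer counts and 6204 luminal and 5866 basal genes tested, luminal lobe counts were 2023, 1258, 1726 and 2695 (anterior, dorsal, lateral, ventral). Strain counts by lobe were 390, 206, 1119 and 144 and the interaction 240. Basal anterior and dorsal counts were 1155 and 218. The basal ventral count was 201 with at least 50 cells per sum and 214 without the ventral library rich in interferon genes; the cause was not tested.

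With each mouse left out, counts ranged from 4059 to 6487 for luminal dorsal. For strain in the anterior, dorsal, lateral and ventral lobes they were 826 to 2018, 1122 to 2627, 1823 to 3859 and 838 to 1960, with 453 to 2252 for the interaction and 1711 to 4647 for strain over lobes. They were 995 to 1928, 187 to 769, 186 to 515 and 134 to 315 for basal anterior, dorsal, lateral and ventral and 196 to 514 for fibroblast lobes. They were 1018 to 2018, 39 to 264 and 20 to 132 for basal, fibroblast and myeloid strain, and 1735 to 2898 for proximal cells. Each leaves fewer mice, and without an FVB/NJ mouse the other is assumed to vary like the other groups. Differences of shares by lobe with a mouse left out, in percentage points, ranged from -19.6 to -15.2 for ventral basal, 9.07 to 15.5 for ventral proximal, 8.99 to 12.9 for anterior fibroblast, 0.799 to 1.33 for anterior myeloid, 1.58 to 2.75 for lateral smooth muscle and -1.13 to -0.924 for ventral endothelial cells. With 4 mice there are fewer arrangements, and 17 of 160 shares then became weaker by adjusted p of the exact permutation test.

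With shares taken within epithelial or within other cells, differences were -20.8 for ventral basal (adjusted p = 0.0563 in the exact permutation test), and -14.3 for anterior and 40.8 for ventral myeloid cells, both reversed. The cause was not tested. By strain they were -14.2 for myeloid, 19.9 for smooth muscle and 6.56 for ionocyte-like cells. With at least 1000 genes per cell the strain differences were -24.5 for secretory and 8.24 for proximal luminal-like cells. With at most 10% mitochondrial UMIs the difference was 0.486 for ionocyte-like cells; the cause was not tested. The myeloid strain difference was not run with lobes averaged or with at least 50 cells per sum, since too few libraries or mice remained.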

Other observations

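The search for T-cell and plasma-cell RNA in this part was chosen after the data were seen. Lymphoid RNA lay in the fibroblast class: at resolution 2, 46 cells formed a cluster led by T-cell genes, and 26 of them belonged to the 1220 fibroblast-like cells (2.13%), each in cluster 10, and 20 to secretory luminal-like cells. Without the 29 fibroblast-like cells that held T-cell or plasma-cell RNA, 601 genes differed between anterior and dorsal fibroblast-like cells and 216 between strains. Cells of other classes held secretory transcripts of the luminal-like cells of their lobe, such as Sbp in ventral basal-like cells (log2 change 10.83), and free RNA in the suspensions was not modelled.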
